A study of Oryza sativa with 6 samples.

How the data were processed

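RNA-seq was performed on the stigma, the pollen-receiving part of the pistil, of field-grown rice (Oryza sativa) of the cultivar II-32B. The 6 libraries were labelled as 3 WT replicates and 3 replicates of her1, which carries a loss of function of HER1. Per the labels' protocols, total RNA was extracted with a column kit for plant tissue and libraries were made with an mRNA-seq kit. The labels do not say whether replicates came from separate plants or pools of plants, so p-values measure the spread between these samples, which may be in part technical.

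The authors deposited a table of raw counts per locus and a table of FPKM values (fragments scaled by locus length and library total), each with 1 column per library. The submitters' processing notes name HISAT2 (an aligner), SAMtools, featureCounts (a read counter) and edgeR, without versions or settings. The genome build, the annotation version, the strand setting and the treatment of reads that match several loci are not given in the sources used here. Reads from overlapping loci, antisense partners or near-identical copies therefore cannot be assigned with certainty. The counts were whole numbers that summed to 15087177 to 17368358 per library. Dividing count by deposited FPKM and library total gave a locus length that varied between libraries by at most 0.115% (coefficient of variation, loci above 20 FPKM), so the FPKM values were scaled to the total of the same counts.

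Both tables listed the same 55801 loci under LOC_Os identifiers, with no symbols or descriptions. None of these identifiers matched the RefSeq gene table used here (0 matches), so the files do not pair loci with names and individual genes are not named. The 30 lists planned by product description had no members for that reason and were not tested. Groups of genes were followed through lists of locus identifiers instead. Of these, 3 lists (floral organ identity, grain and stigma size, tapetum) were fixed before the data were examined. A further 12 lists were written after the tables were opened and before any comparison between genotypes was computed. The lists hold 237 loci, and 2 loci belong to both the cytokinin and the grain and stigma size lists. List loci that did not pass the filter on low counts were not tested, and 2 listed identifiers were not among the 55801 loci. List membership rests on general knowledge of rice locus identifiers and could not be checked against an annotation. The digits directly after LOC_Os were read as the chromosome and the order of identifiers as the order along it.

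Counts were tested with edgeR 4.0.16 (R 4.3.3), with TMM scaling, the default filter on low counts (21991 loci kept, holding 99.86% to 99.9% of the counts of each library), a robust quasi-likelihood fit of genotype with no further covariate, and a two-sided quasi-likelihood F test. P-values were adjusted by the Benjamini-Hochberg method over all tested loci, with a threshold of 0.05. "Rose" and "fell" refer to loci past that threshold, and a change of at least 2-fold requires in addition an absolute log2 fold change of at least 1. Standard errors of log2 fold changes were derived from the F statistic. CPM values are counts scaled to the TMM-adjusted library total. The 12 lists with at least 5 tested loci were compared with all other tested loci by camera (limma 3.58.1, preset correlation 0.01, adjusted over the 12 lists). Camera with an estimated correlation was run beside it, as was fry, which asks whether a list's loci move on balance one way without comparing them with other loci. Camera with an estimated correlation also uses the few residual degrees of freedom of the 6 libraries. Its p-values can therefore be larger even where the correlation is low.

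Loci printed by identifier were set by rule before the data were examined. They had to pass the threshold, show no overlap of CPM between genotypes and have a mean count of at least 50 in the higher genotype. As identifiers could not be paired with names, the 2 with the largest rise and the 2 with the largest fall are given. Alternatives were DESeq2 1.42.0, limma-voom, RLE and upper-quartile scaling, no filter and a filter of 1 CPM in 3 samples, the replicate number as a block, limma on log2(FPKM + 1) and log2(FPKM + 0.1), and leaving out each library in turn. Plain library-size scaling, the removal of a trend on locus length or on abundance (a smoothed curve per library, entered as offsets) and shuffles of locus positions within chromosomes were added after the data were seen. A zero in 1 library allows up to 0.173 to 0.199 CPM (3 counts of its total). Such limits cover counting error only.

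The edgeR step was tested on data simulated from the means and library sizes of these 21991 loci, with 200 loci changed in each of 4 simulations. With dispersions on the fitted trend, 64.6% of loci changed 1.5-fold, 84% of those changed 2-fold and 96.2% of those changed 4-fold were recovered, and 4.7% of calls were false. With locus-wise dispersions the false share was 8.7%, above the nominal level, and the recovered shares were 61.2%, 82.1% and 96.6%. The real comparison called far more loci (8003), many of them changed by less than 1.5-fold, a size that was not simulated. These shares therefore describe the simulated setting and not the real comparison.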

Results

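Transcript levels were compared between WT and her1 stigmas in 3 replicates of each genotype. II-32B is a maintainer line used in hybrid rice breeding. The libraries held 15520859 to 17368358 counted reads in WT and 15087177 to 15812747 in her1. At least 1 count was seen at 26337 to 26648 loci per WT library and at 27037 to 27141 loci per her1 library. Replicates of a genotype correlated at 0.987 to 0.991 (Pearson, log2 CPM across loci, which are not independent replicates) and pairs of different genotypes at 0.956 to 0.965. No pair of libraries was alike within sampling noise, since the chi-square of counts per degree of freedom was 2.1 to 5.55 within a genotype and 15.09 to 26.27 between genotypes. The first principal component held 69.1% of the variance and separated the genotypes. On the second, with 11% of the variance, WT replicate 3 lay apart from the other WT libraries (-28.6, against 10.6 and 11.9). The her1 libraries were spread along it (20.9, -16.8 and 1.9 for replicates 1, 2 and 3). The labels give no locus for HER1, so its own transcript was not checked.

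The her1 stigma differed from WT at a large share of its expressed loci, mostly by small amounts. Of 21991 tested loci, 8003 changed (36.4%; edgeR quasi-likelihood test, adjusted p below 0.05), of which 4224 rose and 3779 fell in her1. The median absolute log2 fold change of these loci was 0.42, and 2108 of the rises and 2945 of the falls were smaller than 1.5-fold. Changes of at least 2-fold were mostly rises, with 1209 loci higher and 323 lower, so that rises made up 78.9%. When a trend on abundance was removed from each library, 891 loci rose and 524 fell at least 2-fold (63% rises). The median log2 fold change over all tested loci was 0.

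The large changes lay mainly among scarce transcripts, which were also higher in her1 as a class. The tested loci were ordered by mean abundance and divided into 5 equal bins. The median log2 fold change was 0.26 in the lowest bin and -0.04 to 0.05 in the others. In the lowest bin (median 1.7 CPM), 742 loci rose and 182 fell at least 2-fold, whereas in the highest bin (median 104.7 CPM) 15 rose and 5 fell. Counting changes of any size, the highest bin leaned the other way, with 775 rises and 1329 falls. The most abundant locus took 1.34% ± 0.062 of the counts in WT and 0.797% ± 0.031 in her1 (SD, n = 3), a log2 fold change of -0.78 (SE 0.05, edgeR adjusted p = 9.9e-12).

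**Figure D1:**
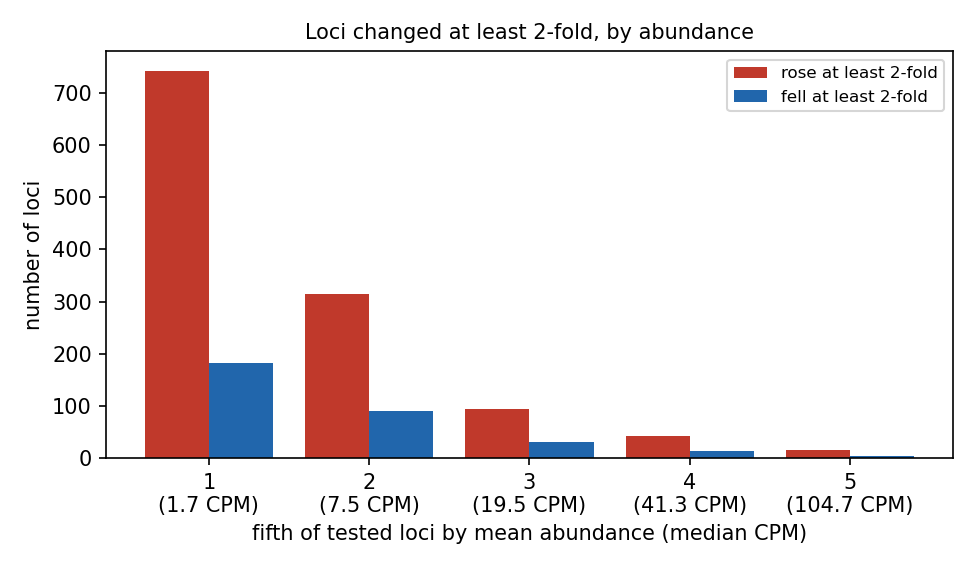
Number of tested loci that rose (red) or fell (blue) at least 2-fold in her1 (y axis), in 5 equal bins of the tested loci by mean abundance (x axis, with the median CPM of each bin). Rises outnumbered falls in every bin, from 742 against 182 in the lowest to 15 against 5 in the highest.

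The 2 loci with the largest rise under the rule fixed beforehand had no counts in WT. LOC_Os11g20310 on chromosome 11 had 0 counts in the 3 WT libraries and 13.1 ± 0.78 CPM in her1 (SD, n = 3), at least 214-fold higher when WT is set to the limit of 3 counts over the group (edgeR adjusted p = 2.28e-13). LOC_Os07g22494 on chromosome 7 also had 0 WT counts and reached 5.05 ± 1.3 CPM in her1, at least 82-fold higher on the same basis (edgeR adjusted p = 1.76e-09). The largest falls were at LOC_Os01g41810 on chromosome 1, from 16.6 ± 0.99 to 0.828 ± 0.16 CPM (log2 fold change -4.31, SE 0.19, edgeR adjusted p = 7.52e-14), and at LOC_Os06g51050 on chromosome 6, from 8.9 ± 1 to 0.444 ± 0.27 CPM (log2 fold change -4.29, SE 0.29, edgeR adjusted p = 1.19e-10). The latter belongs to the list of pathogenesis-related protein and chitinase loci. The lists described next rest on general knowledge of rice locus identifiers, and their membership was not checked against an annotation.

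Diterpenoid phytoalexin synthesis showed the largest fall of any list. Diterpenoid phytoalexins are antimicrobial compounds of rice. Of 11 tested loci, 10 fell and none rose, with log2 fold changes of -3.73 to -0.92, and 9 fell at least 2-fold. The same 10 to 0 split was found when p-values were adjusted over the list alone. The list mean fell by 2.32 ± 0.12 on the log2 scale (SD over 3 her1 libraries; SD 0.08 over 3 WT libraries). The median level was 5.85 CPM in WT and 0.703 CPM in her1. The fall passed camera (adjusted p = 6.07e-08), and it held with an adjusted p = 0.0484 with an estimated correlation. In the same her1 libraries the photosynthesis list, a marker of green tissue, was higher by 0.49 ± 0.02. The other loci of this list had too few counts to test. All 11 tested members lie in 2 short stretches of identifiers, on chromosomes 2 and 4, so they need not vary independently. Reads of near-identical copies cannot be assigned with certainty.

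Other defence loci moved in both directions. Of 12 tested pathogenesis-related protein and chitinase loci, 3 rose and 5 fell (also 3 and 5 adjusted over the list alone), with log2 fold changes of -4.29 to -0.67 among the falls. Of the 3 that rose, 1 went from 8.93 to 31.4 CPM (log2 fold change 1.81, edgeR adjusted p = 2.22e-09) and another from 9.34 to 36.6 CPM (SE 0.46 on the log2 scale, edgeR adjusted p = 0.0342). The remaining rise had 3 counts in WT and 95 in her1, a ratio of 33 (95% exact counting interval 10.9 to 163). The list as a whole did not pass camera (adjusted p = 0.132). Of 9 tested WRKY transcription factor loci linked to defence, 4 rose by 0.76 to 2.72 and 1 fell by 0.97 on the log2 scale (5 and 3 adjusted over the list alone), and the list did not pass camera (adjusted p = 0.442).

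Cell cycle and DNA replication loci were lower in her1. Of the 19 tested loci of this list, 15 fell and none rose. Log2 fold changes of the falls were -1.24 to -0.38, and 18 loci fell when adjusted over the list alone. The list mean fell by 0.66 ± 0.05 in her1, against an SD of 0.05 in WT (log2 scale, n = 3). Camera gave an adjusted p = 1.11e-09, and the call was lost at an adjusted p = 0.0869 with an estimated correlation. The photosynthesis marker was higher by 0.49 ± 0.02 in these her1 libraries.

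Photosynthesis loci rose together in her1. The list was compiled for light-harvesting proteins, photosystem subunits and the small subunit of Rubisco, and all 30 loci passed the filter on low counts. Of these, 24 rose and none fell (25 and 0 adjusted over the list alone), by 0.13 to 1.49 on the log2 scale, and 4 rose at least 2-fold. The median level was 79.8 CPM in WT and 105 CPM in her1. Camera gave an adjusted p = 1.17e-08, and the call was lost at an adjusted p = 0.0869 with an estimated correlation.

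Circadian clock loci, included as a marker of the time of harvest, were lower on balance. Of 11 tested loci, 8 fell (log2 fold changes of -1.89 to -0.20) and 2 rose (0.22 to 0.66) (8 and 2 adjusted over the list alone). Camera gave an adjusted p = 0.00197, and the call was lost at an adjusted p = 0.427 with an estimated correlation. The photosynthesis marker was higher by 0.49 ± 0.02 in the same libraries.

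**Figure D2:**
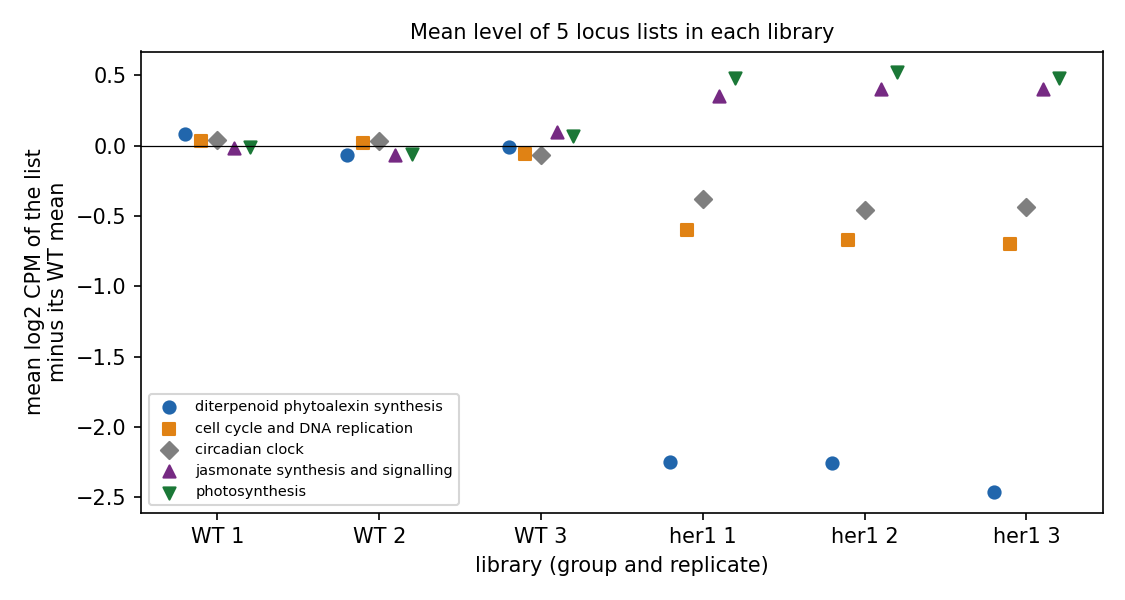
Mean log2 CPM of the loci of 5 lists in each of the 6 libraries (x axis), relative to the mean of the 3 WT libraries (y axis), 1 point per list and library. WT libraries lie within 0.10 of their mean, whereas her1 libraries lie at -2.25 to -2.46 for phytoalexin synthesis, at -0.60 to -0.70 for the cell cycle and at 0.48 to 0.52 for photosynthesis.

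More jasmonate loci rose than fell, and 8 of the 18 tested were not called. Jasmonate is a wound and defence hormone, and the list was compiled for its synthesis and signalling. Of the tested loci, 8 rose (log2 fold changes of 0.22 to 1.59) and 2 fell (-0.29 to -0.14) (9 and 2 adjusted over the list alone). Camera gave an adjusted p = 0.0224, and the call was lost at an adjusted p = 0.145 with an estimated correlation. That estimate was -0.05, below the preset 0.01, so correlation among these loci did not account for the loss. The photosynthesis marker was higher in the same libraries, by 0.49 ± 0.02.

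Among gibberellin and cytokinin loci some rose, some fell and many were not called, 7 of 13 in the gibberellin list and 8 of 16 in the cytokinin list. Of 13 tested gibberellin loci, 4 rose (log2 fold changes of 0.29 to 1.24) and 2 fell (-0.93 to -0.75) (adjusted over the list alone, also 4 and 2; camera adjusted p = 0.274). Of 16 tested loci of cytokinin oxidases, cytokinin activation and type-A response regulators, 5 rose (0.59 to 1.82) and 3 fell (-1.18 to -0.17) (adjusted over the list alone, also 5 and 3; camera adjusted p = 0.633). Of the gibberellin loci, edgeR called 6, limma-voom 5 and DESeq2 2. Heat shock protein and heat stress factor loci also split, with 7 of 22 rising (0.24 to 1.64) and 6 falling (-0.89 to -0.12) (7 and 6 adjusted over the list alone; camera adjusted p = 0.727). The median (-0.10) and the mean (0.10) of the heat shock list differed in sign. Its most abundant locus, also the most abundant locus described above, fell from 13535 to 7887 CPM (log2 fold change -0.78). The next most abundant fell from 3467 to 2399 CPM (-0.53), whereas the 7 that rose reached at most 266 CPM in her1.

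Floral organ identity loci, which encode transcription factors that specify the organs of the flower, were abundant and moved in both directions. The median level of the 13 tested loci was 247 CPM in WT and 273 CPM in her1, but their median log2 fold change was -0.03. Of these loci, 4 rose (log2 fold changes of 0.12 to 0.64) and 4 fell (-2.53 to -0.15) (4 and 6 adjusted over the list alone). The largest fall, with a log2 fold change of -2.53 (SE 0.08, edgeR adjusted p = 5.58e-16), was the only change of at least 2-fold in this list, and the list did not pass camera (adjusted p = 0.446).

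Loci known for natural variation in grain or stigma size and in cytokinin-dependent panicle branching mostly did not pass the test. Most tested loci in general did not pass either, as 36.4% of them were called. Of 11 tested loci, 3 rose by 0.53 to 1.02 on the log2 scale, 1 fell by 1.02 (SE 0.20, edgeR adjusted p = 0.000348) and 7 were not called, with the same counts when adjusted over the list alone. The largest rise was 1.02 (SE 0.17, edgeR adjusted p = 6.36e-05). This rise and the fall are the 2 loci shared with the cytokinin list, where they are counted as well. The list as a whole did not pass camera (adjusted p = 0.398).

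Markers of other tissues that a stigma dissection can carry were scarce, apart from the photosynthesis list. None of 3 tested tapetum loci (the anther's nutritive layer; median 2.74 CPM in WT and 3.85 CPM in her1) passed the threshold in edgeR, DESeq2 or limma-voom, although 2 had an unadjusted edgeR p below 0.05. None of 3 tested pollen beta-expansin loci (1.63 and 1.86 CPM, but a median log2 fold change of -0.13) passed any of these tests. Nor did any of 2 tested endosperm storage protein loci (8.73 and 7.54 CPM). In both lists 0 loci had an unadjusted edgeR p below 0.05. These 3 lists were too short for a list test.

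**Figure D3:**
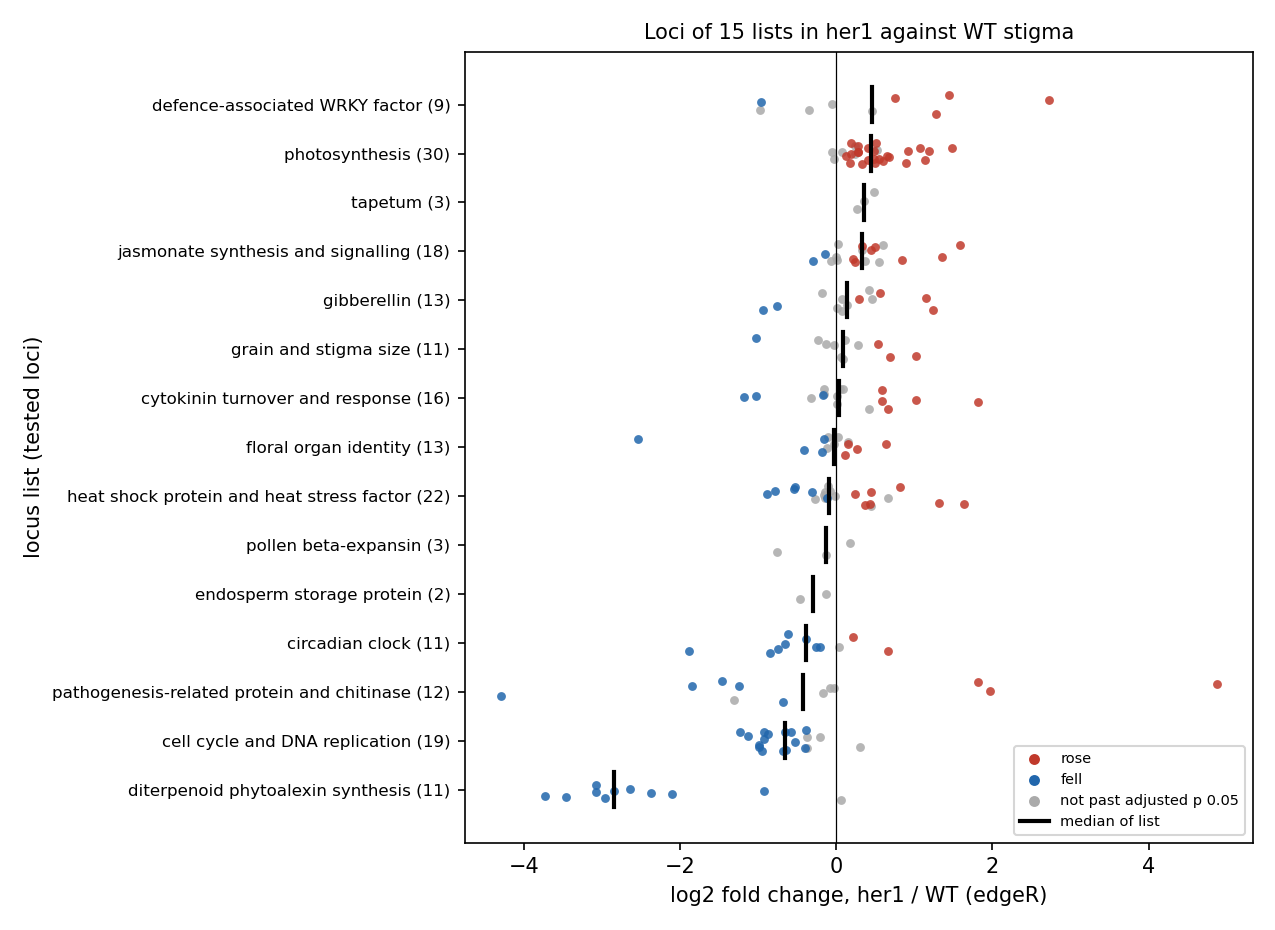
Log2 fold change of her1 against WT (x axis) of each tested locus of 15 lists (y axis, number of tested loci in parentheses). Red points rose, blue points fell, grey points did not pass an adjusted p of 0.05, and black bars are list medians, which run from -2.84 for phytoalexin synthesis to 0.46 for the defence-linked WRKY factors.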

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

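Library-size scaling and the removal of trends on length and abundance were chosen after the data were seen, and the other settings here were planned. Across DESeq2, limma-voom, RLE, upper-quartile and library-size scaling, both filters, the replicate block, both trend removals and the FPKM fits, 6561 to 8848 loci were called and 1360 to 1952 at least 2-fold, except that limma on log2(FPKM + 1) gave 790 loci of at least 2-fold; that pseudocount shrinks the folds of scarce loci, and a pseudocount of 0.1 gave 1481. No called locus changed sign while staying called under any setting. No scaling moved the median of all loci by more than 0.024 (log2) from 0. Leaving out each library in turn gave 6280 to 8433 calls and 1403 to 1825 of at least 2-fold (8433 and 1825 without WT replicate 3, 6743 and 1403 without her1 replicate 2), and left 5 lists past camera each time, the 2 marker lists (photosynthesis and clock) among them. The 4 loci printed by identifier stayed past the threshold in the same direction in all 72 checks. With an estimated correlation, 1 list instead of 5 passed camera (phytoalexin synthesis), and 0 of the 2 marker lists; the adjusted p was 0.0869 for cell cycle, 0.0869 for photosynthesis, 0.427 for clock and 0.145 for jasmonate loci, against 9.33e-10 to 4.19e-09, 6.6e-09 to 1.35e-07, 0.00199 to 0.00317 and 0.0164 to 0.0348 with the preset correlation and a library left out. The estimated correlations were -0.06 for phytoalexin synthesis, 0.15 for cell cycle, 0.07 for photosynthesis, 0.48 for clock and -0.05 for jasmonate loci. As this form of camera also has fewer degrees of freedom, the lost calls cannot be put down to correlation alone. Fry, which tests a list on its own, called 8 lists, adding pathogenesis-related (adjusted p = 0.000178), grain and stigma size (0.004) and floral organ identity (0.000294). The replicate numbers are not stated to mark a shared day or plant, and same-numbered libraries deviated together by correlations of only 0.12, -0.12 and 0.02, with not every library closest to its own number; with the replicate block 8027 loci were called, 1534 at least 2-fold, and no list call changed. At 15087177 to 17368358 counts per library, 21991 of the 31111 loci with a count could be tested. The 6 libraries allow 10 splits of 3 against 3, too few for a share under 0.05. The real split gave 8003 calls and 1532 of at least 2-fold, and the highest of the 9 others gave 0 and 0 (edgeR; up to 1422 loci at an unadjusted p below 0.05), so 1 of 10 splits reached each count. For lists, the real split gave 5 past camera. Each of the 9 others, with 0 called loci, still gave at least 1 list and at most 3. Each of these 9 splits has both genotypes in both of its groups. The genotype difference then adds to the spread within groups and is partly kept between them. Their counts are therefore not those of libraries without a difference, and no conclusion is drawn from them.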

Other observations

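Library-size scaling, the removal of the length and abundance trends and the shuffles within chromosomes were added after the data were seen, and the tests of placement by chance, of the green tissue marker, of the time of harvest and of the surplus of adjacent pairs, with the definition of loci without expression, were chosen after the results they concern had been seen. A set of loci was expressed in one genotype and not detected in the other. With no detection defined as at most 1 count over the 3 libraries and expression as at least 30 counts, 52 loci of the whole table were expressed in her1 only and 8 in WT only. Of the 52, 37 had no WT count at all, the median her1 level was 1.04 CPM and the highest was 13.1 CPM. They included 14 loci on chromosome 11, 9 on chromosome 4 and 8 on chromosome 7. These chromosomes hold 1187 (5.4%), 1900 and 1650 of the 21991 tested loci. The 52 were drawn from all 55801 loci and not from the tested ones, so these numbers are not a matched base for them. Of the 52, 34 were tested and called at least 2-fold higher by edgeR. Rises of at least 2-fold also varied by chromosome, from 4.2% of tested loci on chromosomes 1 and 3 to 9.6% on chromosome 11, while falls of that size ran from 0.8% on chromosome 12 to 2.5% on chromosome 4.

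Among changes of at least 2-fold, rises were 77.8% of calls with a mean count of at least 50 (658 rises and 188 falls), which argues against the noise of low counts as the whole cause of their predominance, and 76.9% after a trend on locus length was removed, which argues against length bias. Scaling stays open, since rises made up at least 78.7% under TMM, RLE, upper-quartile and library-size scaling but these moved the median of all loci by at most 0.024 (log2). Removing a trend on abundance from each library lowered the share to 63%, so a part of the predominance goes with the rise of scarce loci as a class, and a bias that depends on abundance cannot be told apart from an effect of the genotype, because the trend differs between the genotypes. Green tissue carried into the her1 libraries may contribute and cannot be told apart from a change within the stigma: the photosynthesis list had a median log2 fold change of 0.45, but nothing in the tables says which of the rising loci belong to green tissue.

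Loci that rose at least 2-fold lay next to each other more often than abundance-matched shuffles allowed, with 141 adjacent pairs against a mean of 72.4 and a maximum of 103 in 1000 shuffles (permutation p = 0.001, the smallest they can give). Shuffles that also kept each chromosome's own rate gave a mean of 76 and a maximum of 98. Reads shared by overlapping or tandem copies may contribute and cannot be told apart from local co-regulation, because no annotation of these loci was used here, and 54 more pairs were adjacent than 10 tested loci apart. Pairs of rises 2, 5 and 10 tested loci apart numbered 105, 84 and 87 (permutation p = 0.001, 0.007 and 0.009 in the shuffles by abundance). The count at 10 passed the bound set for it beforehand (82), the outcome predicted if shared reads were not the whole cause. The shuffles within chromosomes, added later because the rate of rises differed between chromosomes, gave permutation p = 0.001, 0.062 and 0.02. At 5 tested loci the 84 pairs stayed above the shuffle mean of 70.5, but the call was lost. At 10 tested loci, the distance with the bound set beforehand, 87 pairs against a mean of 69.3 still passed, narrowly (bound 86). Without an annotation, copies that share reads could also lie 10 tested loci apart. The pairs at 10 therefore cannot decide the part played by shared reads, which is left open. No window of 30 tested loci was denser than the densest window of the shuffles (13 rises at most, on chromosome 11, against 14). Thus 0% of the rises lay in such windows, which argues against a few dense segments of that length holding most rises. Shorter runs of neighbouring rises were not tested by these windows and are left open. Falls were also adjacent more often than in the shuffles (20 pairs against a mean of 5, permutation p = 0.001). However, pairs of falls 10 tested loci apart did not pass the test (7 against a mean of 4.8, permutation p = 0.19). Within chromosomes they did not pass either (permutation p = 0.26). The densest window of falls, on chromosome 4, equalled the densest of the shuffles (7 falls). The falling phytoalexin loci, in short stretches on chromosomes 2 and 4, were not left out of these counts. The placement of falls may therefore in part repeat the fall of that list.

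The rise of photosynthesis loci together with the fall of cell cycle loci did not rest on a single library, since both lists kept an adjusted camera p of at most 1.35e-07 when each library was left out. Both calls were lost with an estimated correlation (camera adjusted p = 0.0869 for each list). A different time of day at harvest may contribute: the clock list had a median absolute log2 fold change of 0.62, against 0.21 over all tested loci. The labels record no harvest time or flower stage, so this cannot be told apart from an effect of the genotype or of the age of the stigma.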
